A study of Mus musculus with 12 samples.

How the data were processed

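Fibroblasts were sorted from enzyme-digested lungs of mice whose Pdgfra gene carries a GFP reporter. Bright and dim cells were collected 5 days after a sham operation, a pneumonectomy, or a pneumonectomy in mice that express a dominant-negative FGF receptor 2. RNA of 2000 sorted cells per sample was amplified over 25 cycles and hybridized to Affymetrix mouse arrays. There are 12 arrays in 6 groups of 2. The labels call the replicates biological, and whether each is 1 animal or a pool is not stated, so p-values here measure the spread between these samples. Bright and dim arrays were treated as independent, though both gates may come from the same animals. In means over both subsets p-values may then be too small. The number of arrays limits the precision: the residual standard deviation over the genes tested had a median of 0.199 log2.

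The deposited values are log2 signals, which per the submitters' processing notes were made with RMA (background correction, quantile normalization and summary of probes); its version and options are not given in the sources used here. They ranged from 1.5 to 13.05, with array medians of 5.06 to 5.13, 0 missing values and 0 duplicated columns, and were used as they are.

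Of 45141 probe sets, 104 controls were left out. The array's annotation gave 1 gene for 28898 probe sets, several for 551 and none for 15588. Symbols of 28689 of the 29449 annotated probe sets were taken from a gene table by Entrez identifier. Probe sets with several genes or none were not used for gene results. For each of the 17097 genes the probe set with the highest mean over the arrays stood for the gene (7180 had more than 1), and a gene was tested if its value exceeded log2 5.101, the median of all values, on at least 2 arrays. That left 11073 genes, with 6024 below the filter. Some list members with no named probe set, such as Tagln and Spp1, were not analysed here.

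A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (6 residual and 3.31 prior degrees of freedom), and limma's moderated test gave p-values, adjusted by Benjamini and Hochberg's method over all genes of a contrast. The threshold was an adjusted p below 0.05. All adjusted p-values of genes are from limma. The 14 contrasts were bright against dim cells (in each condition and as the mean over the 3), each pair of conditions within each subset, 2 pairs as the mean over both subsets, and 2 differences of effects between the subsets. The 31 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at a correlation estimated from the data, and with fry, each adjusted over the lists. Counts of members past the threshold are given with adjustment over all genes and, separately, over the list alone.

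The contrasts, filters, gene lists, alternatives and the rule for named genes were set before the data were examined. Per contrast, the rule takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays do not overlap between the groups compared, leaving out predicted genes. Where fewer than 6 genes pass, it adds the 3 largest rises and 3 largest falls at an unadjusted p below 0.01, given as values that did not pass. For the 2 differences of effects overlap was not examined. It also takes up to 4 members per list with the smallest adjusted p among those past the threshold, up to 2 members with the highest level where none passes, the 2 members with the highest level of each list of another cell type, and Pdgfra, Fgfr2, Acta2, Plin2, Col1a1, Eln and Mki67 always. Not every gene that it takes is named. Genes outside it are said to be chosen after their values were seen.

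The alternatives were no filter, a stricter filter (log2 6.762, the 75th percentile), another round of quantile normalization, the mean of a gene's probe sets, a variance trend, only the arrays of the groups compared, replicate blocks, and each array left out in turn. Leaving out arrays from the list tests and from the clock gene test was added after the data had been seen, as was setting every value below the filter to the filter's value for the named genes and for 2 of the lists. The fit was tested on simulated data with known changes. At a change of 1 log2 it recovered 91% of changed genes for bright against dim cells as the mean, 38.8% for PNX against SHAM in 1 subset, 88.1% for the mean over both subsets and 13.4% for a difference of effects. Random draws used the seed 20.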

Results

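Gene expression was measured on 12 arrays of fibroblasts sorted from digested mouse lungs. The animals carried GFP as a reporter of the gene for PDGF receptor alpha (Pdgfra), and the sort kept a bright and a dim GFP gate, each with 2000 cells per sample. Lungs were taken 5 days after surgery. The surgery was a sham operation (SHAM), a partial pneumonectomy, the removal of part of the lung after which the rest regrows (PNX), or a pneumonectomy in animals that express a dominant-negative FGF receptor 2 (PNX-dnFGFR). Each of the 6 groups had 2 arrays, labelled biological replicates. The median log2 signal per array lay between 5.06 and 5.13, and 11073 genes were tested.

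The 2 subsets were the main division of the arrays. Across genes, which are not independent replicates, Pearson's r was 0.953 to 0.976 between arrays of a group, 0.915 to 0.977 between conditions of a subset, and 0.787 to 0.893 between bright and dim arrays. The first principal component held 66.1% of the variance and separated all bright from all dim arrays, and the second held 8.9%. On the second component the bright SHAM arrays were at 15.1 and 34.2 and the bright PNX-dnFGFR arrays at -24.2 and -17.1. The bright PNX arrays lay apart from each other, at -10.5 for replicate 1 and 20.7 for replicate 2.

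Which genes distinguish bright from dim cells was asked first, as the mean over the 3 conditions. Scara3 was higher in bright cells by 6.80 log2 (± 0.18 SE, n = 6 arrays per subset, adjusted p = 1.7e-08), from 3 groups of bright arrays against 3 of dim arrays. Lum, which encodes the matrix proteoglycan lumican, was higher by 5.77 (± 0.13, adjusted p = 7.7e-09), and Cyp1b1 by 6.64, Scara5 by 6.14, Ildr2 by 5.73, Rbp4 by 5.64, Cxcl13 by 5.34, Aldh1a2 by 5.21, Rian by 5.19 and Penk by 5.14. Slc7a10, an amino acid transporter gene, was lower in bright cells, with a log2 difference of -5.68 (± 0.10, adjusted p = 1.5e-09), followed by Fat3 at -4.55, Scn3a at -4.38, Mapt at -4.28, Scube2 at -4.23, Fgfr4 at -4.18, Ces1d at -3.93, Gja5 at -3.66, Prkg2 at -3.56 and Cdo1 at -3.55. In every condition both bright arrays lay on 1 side of both dim arrays for these 20 genes, which the rule for named genes requires. Some of them lay near the lower end of the signal in the other subset, such as Scara3 at 2.21 to 3.16 on the dim arrays, below the filter's log2 5.101. Signals that low are not shown to lie above background, so the size and rank of such differences are uncertain. With every value below the filter set to it, chosen after the data had been seen, Scara3 had 4.51, Cyp1b1 5.18, Scara5 4.02, Lum 3.32, Ildr2 4.2, Rian 3.87, Slc7a10 -5.30 and Fat3 -3.88. For the other genes of the report this second value, called the held value below, is given where the first is more than 1.5 times as large. It was not computed for values given only where clock and glucocorticoid genes are discussed, so those were not checked against the filter. Acta2, the gene of smooth muscle actin, was higher in bright cells by 2.15 (± 0.26, adjusted p = 0.00013), the proliferation marker Mki67 by 2.18 (± 0.39, adjusted p = 0.0015, held value 1.45), Fgfr2 by 1.45 (± 0.21, adjusted p = 4e-04) and Col1a1 by 0.41 (± 0.07, adjusted p = 0.0013). Plin2, which encodes a lipid droplet protein, was lower, at -1.29 (± 0.12, adjusted p = 2.8e-05), and Eln did not pass (0.16 ± 0.09, adjusted p = 0.16). Pdgfra itself was lower in the arrays labelled bright, at -1.75 (± 0.10, adjusted p = 9.9e-07). Its signal was 4.84 to 5.54 on the 6 bright arrays and 6.66 to 7.13 on the 6 dim arrays, from the only probe set named for it. Of all genes, 3152 were higher and 2141 lower in bright cells by limma, 930 and 513 of them over 2-fold.

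**Figure D1:**
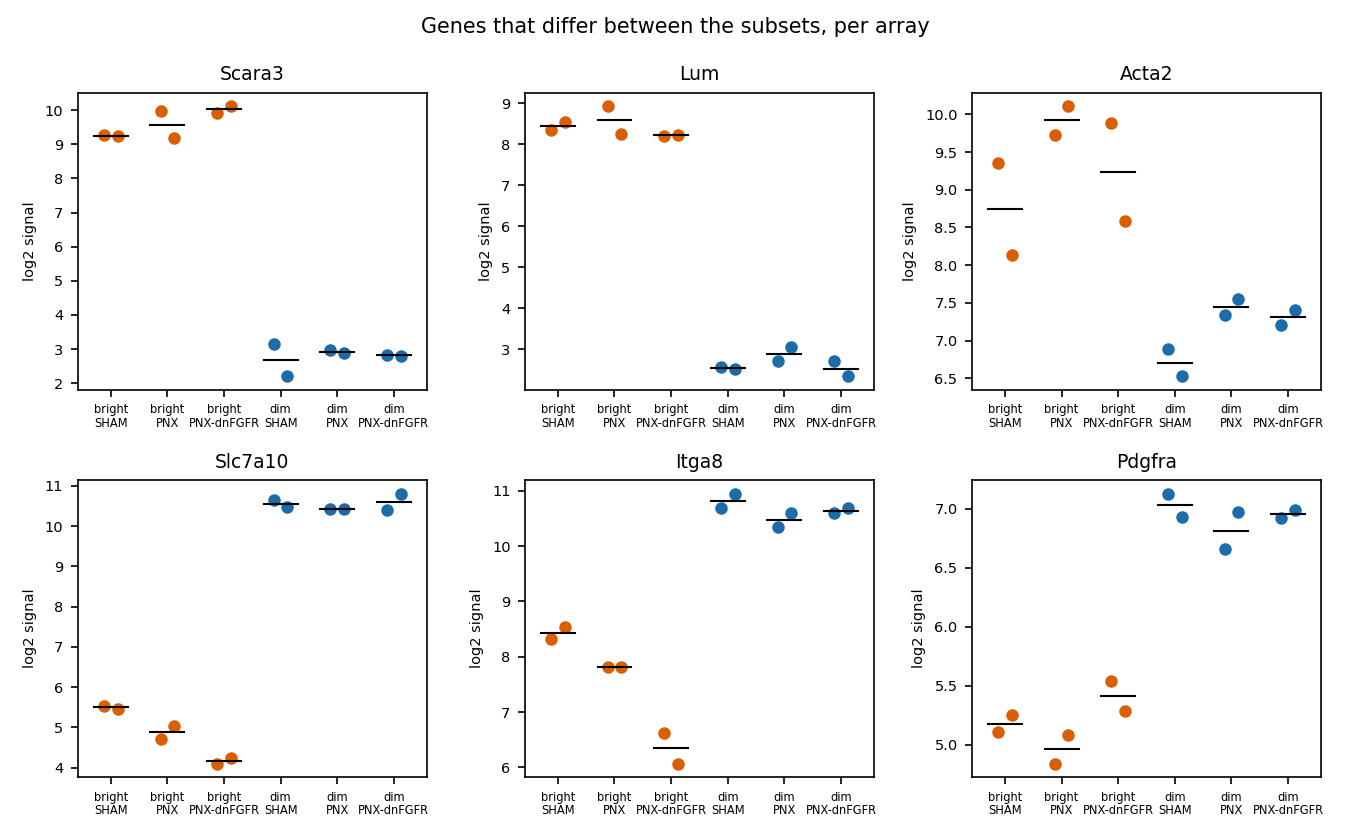
Log2 signal of 6 genes on each array (points, 2 per group) with the group mean (line), for bright (orange) and dim (blue) cells of the 3 conditions. Scara3, Lum and Acta2 were higher and Slc7a10, Itga8 and Pdgfra lower on the bright arrays, Pdgfra lying at 4.84 to 5.54 there and at 6.66 to 7.13 on the dim arrays.

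Gene lists of fibroblast types were compared between the subsets first. Of 19 adventitial fibroblast genes, 16 were higher and 2 lower in bright cells (16 and 2 adjusted over the list alone), led by Lum, Scara5, Serpinf1 (4.58) and Igfbp4 (2.56), with a median of 2.20. The competitive set test camera called this list at an adjusted p of 5.5e-07, and at 0.031 with an estimated correlation. Of 17 alveolar fibroblast genes, 14 were lower and 1 higher (15 and 2 adjusted over the list alone), led by Slc7a10, Scube2, Itga8 (-3.12) and Fgfr4, with a median of -1.92. Their adjusted p was 1.2e-08 by camera, and adjusted p = 0.12 with an estimated correlation. Of 13 alveolar myofibroblast genes, 10 were higher and 3 lower (10 and 3 adjusted over the list alone), with Aspn at 2.86 (held value 1.47), Fgf18 at 3.01 and Hsd11b1 at -2.73. The camera adjusted p was 0.035, and adjusted p = 0.29 with an estimated correlation. Without bright PNX replicate 2, left out after the data had been seen, the myofibroblast list no longer passed (adjusted p = 0.057). The lipofibroblast and lipid storage list had 9 of 16 genes lower and 4 higher (9 and 5 adjusted over the list alone), with Dgat2 at -2.43, G0s2 at -2.52, Tcf21 at -2.71 and Fst at 2.73. Its adjusted p was 0.023, and adjusted p = 0.46 with an estimated correlation. Pericyte genes went both ways, 4 of 8 higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.43), with Kcnj8 at 4.85 (held value 3.08), Pdgfrb at 3.23 and Gucy1b1 at -2.81. Contractile genes did so too, 6 of 14 higher and 5 lower (6 and 5 adjusted over the list alone, adjusted p = 0.86), with Myl9 at 2.80, Tpm2 at 1.98, Cnn2 at -0.84 and Vcl at -1.28.

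Lists of matrix genes were compared as well. Of 21 matricellular and matrix turnover genes, 14 were higher and 4 lower (14 and 4 adjusted over the list alone), among them Postn (2.85), Vcan (3.34) and Ccn5 (-2.80), with an adjusted p of 0.015 by camera and adjusted p = 0.38 with an estimated correlation. Of 24 collagen genes, 13 were higher and 4 lower (13 and 4 adjusted over the list alone, adjusted p = 0.064), with Col15a1 at 4.42, Col14a1 at 3.70, Col5a3 at 3.45 and Col13a1 at -2.85. The collagens passed without bright PNX-dnFGFR replicate 2 (adjusted p = 0.025) or dim PNX-dnFGFR replicate 1 (adjusted p = 0.027). Of 17 elastic fibre genes, 8 were higher and 6 lower (8 and 6 adjusted over the list alone, adjusted p = 0.53), with Mfap5 at 2.20, Mfap2 at 2.17, Loxl2 at 1.75 and Fbln1 at 1.74.

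Signalling genes were split by pathway. The 12 hedgehog pathway genes had 10 higher and 1 lower (10 and 1 adjusted over the list alone), with Cdon at 3.36, Gli1 at 2.43, Gas1 at 1.40 and Foxf2 at -2.20. Their camera adjusted p was 0.0058, and adjusted p = 0.46 with an estimated correlation. Of 12 IGF axis genes, 7 were higher and 2 lower (7 and 2 adjusted over the list alone), led by Igfbp5 at 4.41 and Pappa at 2.25, with an adjusted p of 0.015, and adjusted p = 0.29 with an estimated correlation. PDGF and FGF pathway genes were more often lower, 9 of 19 against 3 higher (10 and 3 adjusted over the list alone), with Fgfr4 and Pdgfra lower and Pdgfrb and Fgf18 (3.01) higher. That list had an adjusted p of 0.019, and adjusted p = 0.24 with an estimated correlation. Camera did not call 3 other pathways. TGF-beta and BMP pathway genes had 9 of 21 higher and 7 lower (9 and 7 adjusted over the list alone, adjusted p = 0.55), with Tgfb3 at 2.43, Inhba at 2.88 (held value 1.69) and Bmp4 at -1.50. Wnt pathway genes had 10 of 18 higher and 4 lower (11 and 4 adjusted over the list alone, adjusted p = 0.23), with Wnt2 at -2.75, Notum at -2.22 and Wnt5a at 2.73. Retinoid pathway genes had 7 of 15 higher and 4 lower (7 and 6 adjusted over the list alone, adjusted p = 0.41), with Rbp4, Aldh1a2 and Adh7 (2.98).

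Cell cycle genes were higher in bright cells in 28 of 34 cases and lower in none (29 and 0 adjusted over the list alone), with Birc5 at 1.72, Rrm1 at 1.16, Prc1 at 2.10 and Ccna2 at 1.71. The list had an adjusted p of 5.5e-07 by camera, and adjusted p = 0.46 with an estimated correlation. Cytokines and chemokines had 12 of 21 higher and 4 lower (12 and 4 adjusted over the list alone), with Il33 at 3.67 (held value 1.82), Cxcl12 at 2.94, Ccl7 at 2.01 (1.02) and Cxcl14 at -1.33. Their adjusted p was 0.044, and adjusted p = 0.46 with an estimated correlation. The cytokine list no longer passed without bright SHAM replicate 1 (adjusted p = 0.058) or dim PNX-dnFGFR replicate 2 (adjusted p = 0.067). Immediate early genes had 13 of 24 higher and 3 lower (16 and 4 adjusted over the list alone, adjusted p = 0.06), with Klf4 at 3.21 and Myc at 2.76. Heat shock and unfolded protein genes had 9 of 21 higher and 3 lower (9 and 3 adjusted over the list alone, adjusted p = 0.29), with Pdia4 at 0.65, and interferon response genes 4 of 17 higher and 3 lower (4 and 2 adjusted over the list alone, adjusted p = 0.89), with Ifit2 at -1.39 and Gbp2 at 1.29. For the interferon list the median was 0.19 while camera's direction was down. Glycolysis and hypoxia genes had 11 of 20 higher and 4 lower (12 and 4 adjusted over the list alone, adjusted p = 0.18), with Pfkp at 1.37 and Vegfa at -1.64. Oxidative phosphorylation genes had 14 of 28 higher and 1 lower (15 and 1 adjusted over the list alone, adjusted p = 0.064), with Ndufa1 at 0.76. Cholesterol synthesis genes had 2 of 17 higher and 6 lower (2 and 7 adjusted over the list alone, adjusted p = 0.05), with Sc5d at -1.88, Msmo1 at -0.63 and Ebp at 0.59. Cholesterol synthesis, at the threshold, passed without bright PNX replicate 2 (adjusted p = 0.026), bright SHAM replicate 1 (0.039), dim PNX replicate 1 (0.023), dim PNX-dnFGFR replicate 1 (0.027) or dim SHAM replicate 1 (0.031). The immediate early list passed without bright PNX-dnFGFR replicate 1 (adjusted p = 0.018), bright SHAM replicate 1 (0.045), dim PNX-dnFGFR replicate 2 (0.031) or dim SHAM replicate 2 (0.031).

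Transcripts of other lung cell types were read on all arrays. Sftpc lay at 11.36 to 12.43 and Lyz2 at 9.77 to 11.31. Of 18 epithelial genes, 1 was lower in bright cells and 0 higher by limma (1 and 0 adjusted over the list alone, camera adjusted p = 0.39), and that was Hopx at -2.20. Endothelial genes had 2 of 17 higher and 6 lower (2 and 6 adjusted over the list alone, adjusted p = 0.25), with Tek at 2.89. Macrophage and dendritic cell genes had 1 of 23 higher and 4 lower (1 and 3 adjusted over the list alone, adjusted p = 0.23), with Cd14 at 1.52 (the macrophage list had an adjusted p of 0.02 without dim SHAM replicate 2). Lymphocyte genes were lower in 5 of 12 cases and higher in none (5 and 0 adjusted over the list alone), with Cd3d at -0.70, an adjusted p of 0.015, and adjusted p = 0.46 with an estimated correlation. Mesothelial genes moved with the adventitial ones, 7 of 11 higher and 0 lower (10 and 0 adjusted over the list alone), with Aldh1a2, Nkain4 at 2.71, Igfbp6 at 1.86 and Rspo1 at 1.91 (held value 0.55). Their adjusted p was 0.0087, and adjusted p = 0.56 with an estimated correlation. Of the 8 neutrophil and mast cell genes 1 was higher, Il1r2 at 1.86, and 1 lower, Cpa3 at -1.83 (1 and 1 adjusted over the list alone, adjusted p = 0.54). Their held values were 0.62 and -0.33. Erythrocyte and platelet genes had 1 of 5 higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.67), with Itga2b at 0.39. Glia and neuron genes had 3 of 5 higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.22), with Ngfr at 1.5.

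Pdgfra and Acta2 differed between the subsets in each of the 3 conditions, whereas Fgfr2 and Mki67 did not pass in SHAM. Pdgfra was lower in bright cells by log2 values of -1.85 in SHAM, -1.86 in PNX and -1.54 in PNX-dnFGFR (± 0.17 SE each, n = 2 arrays per group). Acta2 was higher by 2.04, 2.47 and 1.93 in that order (± 0.45 each, adjusted p = 0.012, 0.0046 and 0.0092). With the mean of its probe sets the value in PNX-dnFGFR was 0.68 (adjusted p = 0.21). Without bright SHAM replicate 1 or dim SHAM replicate 2 the Acta2 value in SHAM was 1.44 (adjusted p = 0.078) or 1.87 (adjusted p = 0.072), and without bright PNX-dnFGFR replicate 1 its value in that condition was 1.28 (adjusted p = 0.069). Fgfr2 had 0.70 in SHAM (adjusted p = 0.22), 1.67 in PNX (adjusted p = 0.012) and 1.97 in PNX-dnFGFR (adjusted p = 0.0029), and Mki67 1.28, 2.49 and 2.76 (adjusted p = 0.23, 0.032 and 0.012). Whether the Fgfr2 probe set also reads the transcript of the dominant-negative receptor is not known here. The Fgfr2 value in PNX no longer passed without bright PNX replicate 1 (adjusted p = 0.064) or dim PNX replicate 2 (0.076). Nor did Mki67 in PNX without either bright PNX array (0.14 and 0.069) or dim PNX replicate 2 (0.19), or in PNX-dnFGFR without replicate 1 of either subset (0.08 and 0.075), while in SHAM it passed without dim SHAM replicate 1 (0.022). The held values of Mki67 in SHAM and PNX were 0.51 and 1.40. The genes called by limma numbered 2107 in SHAM (1273 higher, 834 lower), 2042 in PNX (1259 and 783) and 3812 in PNX-dnFGFR (2320 and 1492). Without bright SHAM replicate 2 the SHAM count was 1229, without dim PNX replicate 2 the PNX count was 1110, and without bright PNX-dnFGFR replicate 1 the last was 2429. Of the 34 cell cycle genes, 1 was higher in bright cells in SHAM, 14 in PNX and 30 in PNX-dnFGFR (0, 20 and 30 adjusted over the list alone). The PNX count was 6 without bright PNX replicate 1, and the gene by gene test of a difference between conditions called 0 genes by limma, with 495 genes at an unadjusted p below 0.05 for PNX against SHAM.

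What regrowth after pneumonectomy changes was asked by comparing PNX with SHAM. As the mean over both subsets, Serpina3n, which encodes a secreted protease inhibitor, rose by 2.28 log2 (± 0.15 SE, n = 4 arrays per condition, adjusted p = 6.3e-04), Cthrc1 by 1.56 (adjusted p = 0.014) and the circadian clock gene Per3 by 1.43 (adjusted p = 0.014). Cfi rose by 1.24, Ciart by 1.12, Coq10b by 1.02, Aldh1l1 by 0.89 and the cholesterol synthesis gene Dhcr7 by 0.72 (± 0.09, adjusted p = 0.026). Arntl, another clock gene, fell by 1.66 (± 0.22, adjusted p = 0.037), Spon2 by 0.89 (adjusted p = 0.025), and H3c15, Mmp11, Ms4a4d and Rftn2 had log2 values of -0.91, -0.83, -0.81 and -0.68. For these genes both PNX arrays lay on 1 side of both SHAM arrays in each subset, which the rule for named genes requires. Mpzl2 (-2.59, adjusted p = 0.014) and A330023F24Rik (-1.13, adjusted p = 0.037) also passed and were named after their values were seen. For Mpzl2 the bright PNX and bright SHAM arrays overlap. The held values were 1.07 for Cthrc1, 0.43 for Cfi, -0.36 for H3c15, -1.13 for Mpzl2 and -0.66 for A330023F24Rik. That makes 8 genes higher and 8 lower of 11073, while 1787 genes had an unadjusted p below 0.05. With single arrays left out, between 1 and 16 of these 16 genes still passed: only Serpina3n did without bright PNX replicate 1, bright SHAM replicate 2 or dim PNX replicate 2, and all 16 did without either dim PNX-dnFGFR replicate.

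**Figure D2:**
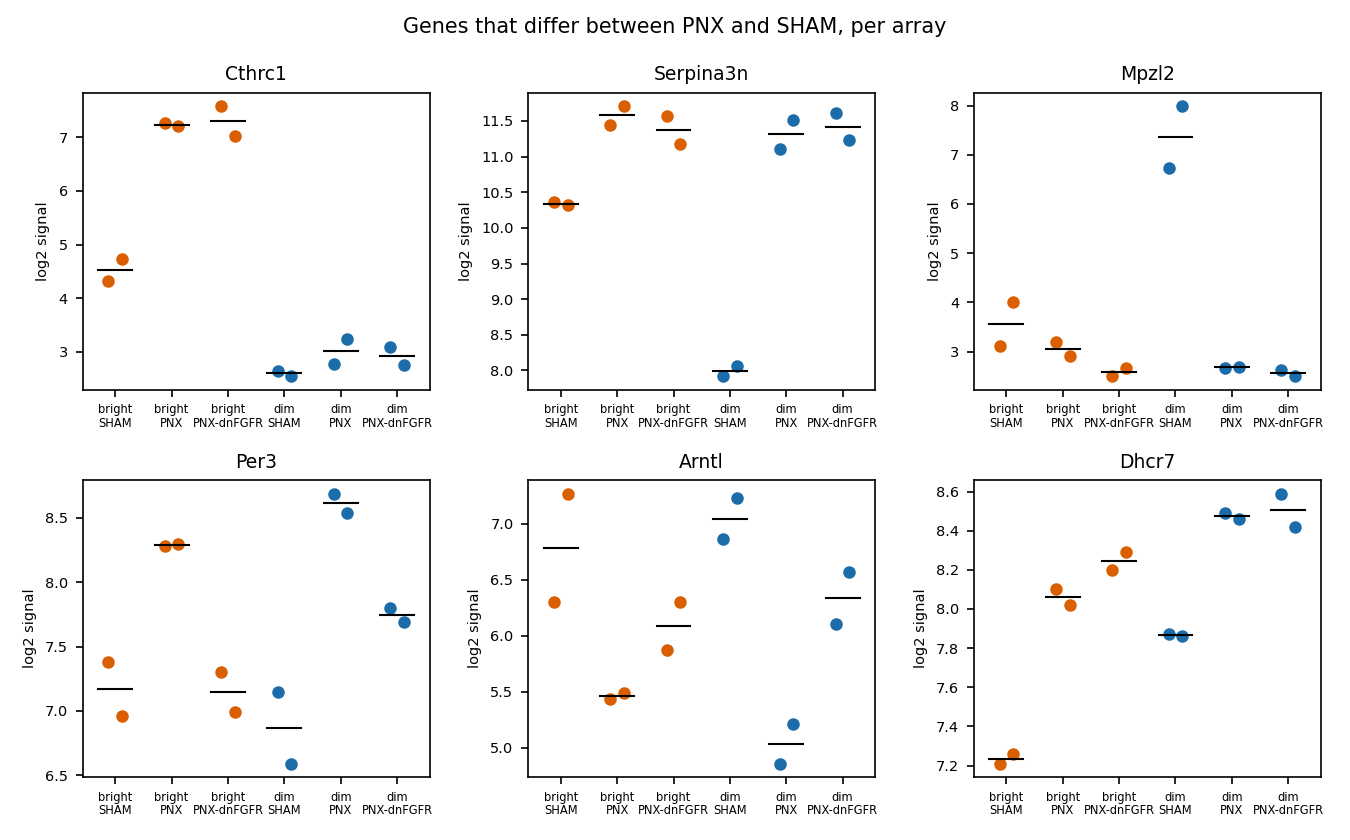
Log2 signal of 6 genes on each array (points, 2 per group) with the group mean (line), for bright (orange) and dim (blue) cells of the 3 conditions. As the mean over both subsets PNX was higher than SHAM in Serpina3n (2.28), Cthrc1 (1.56), Per3 (1.43) and Dhcr7 (0.72) and lower in Mpzl2 (-2.59) and Arntl (-1.66). Mpzl2 lay below the filter on all bright arrays and Cthrc1 on all dim arrays.

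In bright cells alone limma called Cthrc1, which rose by 2.71 (± 0.24, n = 2 arrays per group, adjusted p = 0.0096), and no other gene, with 912 genes at an unadjusted p below 0.05. The Cthrc1 value was 2.68 without bright PNX replicate 1 (adjusted p = 0.13), 2.51 without bright SHAM replicate 1 (adjusted p = 0.054) and 2.91 without bright SHAM replicate 2 (adjusted p = 0.05). With only the groups compared in the fit, limma called 0 genes in bright and 0 in dim cells. Among genes that did not pass were Tnfrsf11b (2.03, held value 1.18, adjusted p = 0.3), Postn (1.93, adjusted p = 0.1), Fbn2 (1.63, held value 0.36), Mlana (-2.22), Zbtb16 (-1.93) and Tmem178 (-1.90). Acta2 did not pass either (1.16 ± 0.45, adjusted p = 0.55). Without bright PNX replicate 2 the count in bright cells was 14 and included Tnfrsf11b (2.68, adjusted p = 0.023), and without either bright PNX-dnFGFR array Postn passed (adjusted p = 0.043). In dim cells Serpina3n rose by 3.33 (± 0.21, adjusted p = 4.8e-04), Ciart by 1.76 and Per3 by 1.74 (adjusted p = 0.049 each), while Mpzl2 fell by 4.67 (± 0.39, adjusted p = 0.0029) and Spon2 by 1.16 (adjusted p = 0.049), and 1346 genes had an unadjusted p below 0.05. Saa3 (5.54, adjusted p = 0.11), Tktl1 (2.72), Nr4a1 (2.17), S100a9 (-3.12), S100a8 (-2.94) and Ddc (-2.27) did not pass. Mpzl2 lay at 2.67 and 2.69 on the dim PNX arrays, below the filter, and its held value was -2.25. Those of Tktl1 and Ddc were 1.18 and -1.05. On the dim SHAM arrays Mpzl2 lay at 6.72 and 7.99, above the filter on these arrays alone. The same arrays had the highest signals of the neutrophil gene S100a9, at 8.39 and 9.26. Whether the fall of Mpzl2 comes from the fibroblasts or from other cells in the dim gate was not tested. Without dim PNX replicate 2 only Serpina3n passed in dim cells, and Mpzl2 had -4.68 (adjusted p = 0.061). Ciart, Per3 and Spon2 lay at the threshold: their adjusted p exceeded 0.05 without most single arrays, bright ones included, such as 0.085 for each without bright PNX replicate 1 or 2.

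Gene lists were compared between PNX and SHAM as well. Cholesterol synthesis genes were higher in PNX, with 1 of 17 past the threshold over all genes and 11 adjusted over the list alone, and a median of 0.45. Camera gave the list an adjusted p of 1.7e-08, and adjusted p = 0.45 with an estimated correlation. Fry, which tests whether a list's genes move 1 way on balance and compares them with no other genes, gave 0.027. Without any single array the camera adjusted p stayed at or below 1.8e-05, although Dhcr7 itself no longer passed without most single arrays, such as bright PNX replicate 1 (0.70, adjusted p = 0.074). The list was called in bright cells (median 0.36, adjusted p = 1.1e-08, with 6 genes higher adjusted over the list alone and 0 over all genes) and in dim cells (median 0.52, adjusted p = 3.2e-05, 5 and 0), with adjusted p = 0.38 and 0.56 with an estimated correlation. Contractile genes had a median of 0.27 over both subsets (0 of 14 past the threshold over all genes and 6 adjusted over the list alone, adjusted p = 0.003, and adjusted p = 0.45 with an estimated correlation). Matricellular genes (median 0.18, 6 of 21 adjusted over the list alone, adjusted p = 0.012) and collagens (median 0.20, 0 of 24, adjusted p = 0.008) were called as well, with adjusted p = 0.62 and 0.64 with an estimated correlation. In bright cells the cell cycle list had a median of 0.61 with 0 of 34 genes past the threshold by limma, over all genes or adjusted over the list alone (camera adjusted p = 3.6e-08, and adjusted p = 0.41 with an estimated correlation). In dim cells heat shock genes (median 0.21, adjusted p = 6.7e-04) and immediate early genes (median 0.30, adjusted p = 0.0037) were higher and neutrophil and mast cell genes lower (median -1.50, adjusted p = 3.8e-05), with adjusted p = 0.56, 0.60 and 0.56 with an estimated correlation. The heat shock call was lost without dim PNX replicate 2 (adjusted p = 0.067) and the immediate early call without dim SHAM replicate 1 (adjusted p = 0.11), in fits chosen after the data had been seen. Mesothelial genes set the bright PNX arrays apart, with a list mean of 1.91 on replicate 1 and -0.29 on replicate 2, against 0.85 and 0.31 in bright SHAM. Of the 31 lists, camera called 10 over both subsets, 0 with an estimated correlation, and fry called 3.

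What the dominant-negative receptor changes after pneumonectomy was asked by comparing PNX-dnFGFR with PNX. In bright cells limma called Stmn2, the gene of a microtubule-binding stathmin, which rose by 2.32 (± 0.23 SE, n = 2 arrays per group, adjusted p = 0.024), and no other gene, with 1390 genes at an unadjusted p below 0.05. Fgfr4 (-1.83, adjusted p = 0.065), Ccn2 (-1.90, adjusted p = 0.089), Frem1 (-1.82), Serpinb2 (3.35, held value 1.98), Aqp3 (3.26) and Rarres1 (2.79) did not pass, nor did Acta2 (-0.68 ± 0.45, adjusted p = 0.6) or Mki67 (1.12 ± 0.68, adjusted p = 0.57). Without bright PNX replicate 1 the fit called 429 genes, among them Fgfr4 (-2.14, adjusted p = 0.012), Ccn2 (-2.45, adjusted p = 0.013), Serpinb2 (4.74), Aqp3 (4.42) and Rarres1 (4.39). The mesothelium list moved with that array: its median was 1.57 in that fit (camera adjusted p = 0.00048), chosen after the data had been seen, and 0.42 with all arrays (adjusted p = 0.17). Stmn2 had 2.02 without bright PNX replicate 2 (adjusted p = 0.18) and 2.44 without bright PNX-dnFGFR replicate 2 (adjusted p = 0.15). It also no longer passed with the mean of probe sets (1.59, adjusted p = 0.061), only the groups compared (adjusted p = 0.37) or a replicate block by number. The same held without either bright SHAM array (0.073) or either dim PNX-dnFGFR array (0.082). In dim cells and over both subsets limma called 0 genes each, with 863 and 1384 at an unadjusted p below 0.05, although 129 were called over both subsets without bright PNX replicate 1. Among genes at an unadjusted p below 0.01 whose arrays do not overlap, the largest values in dim cells were 1.83 for Adamts4 (held value 0.72), 1.51 for Lrat, 1.39 for Spon2 (adjusted p = 0.052), -1.73 for Errfi1, -1.58 for Flrt2 (held value -1.02) and -1.45 for Sytl1. Over both subsets, by the same choice, they were 1.68 for Adamts4, 1.30 for Dhx58, 1.15 for Aurkb, -1.57 for Errfi1 (adjusted p = 0.099), -1.41 for Tsc22d3 and -1.37 for Ccn2 (adjusted p = 0.17).

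Gene lists were compared between PNX-dnFGFR and PNX in each subset, and counts of called lists do not test a difference between the subsets. In dim cells camera called 2 of 31 lists, 0 with an estimated correlation, and fry 0. In bright cells camera called 12, 0 with an estimated correlation, and fry 5. Alveolar fibroblast genes were lower, with a median of -0.70 and 0 of 17 past the threshold over all genes but 11 lower and 1 higher adjusted over the list alone (adjusted p = 8.9e-10, and adjusted p = 0.10 with an estimated correlation). PDGF and FGF pathway genes were lower too (median -0.19, 0 of 19 and 7 adjusted over the list alone, adjusted p = 0.005), as were elastic fibre genes (median -0.42, 0 of 17 and 5, adjusted p = 7.2e-05) and alveolar myofibroblast genes (median -0.84, 0 of 13 and 3, adjusted p = 0.0085), with adjusted p = 0.10, 0.10 and 0.13 with an estimated correlation. Cell cycle genes were higher (median 0.82, 0 of 34 and 8, adjusted p = 1.3e-13, and adjusted p = 0.22 with an estimated correlation), and so were interferon response genes (median 0.44, 0 of 17 and 2, adjusted p = 7.2e-05, and adjusted p = 0.25 with an estimated correlation). Without bright PNX replicate 1, 9 alveolar fibroblast and 5 PDGF and FGF pathway genes passed as lower and 3 cell cycle genes as higher. In dim cells interferon genes (median 0.33, adjusted p = 0.0016) and neutrophil and mast cell genes (median 0.93, adjusted p = 0.0021) were higher, with adjusted p = 0.95 with an estimated correlation for each. Both calls in dim cells were lost without dim PNX-dnFGFR replicate 1 (adjusted p = 0.38 and 0.14) or dim PNX replicate 2 (adjusted p = 0.13 and 0.18).

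**Figure D3:**
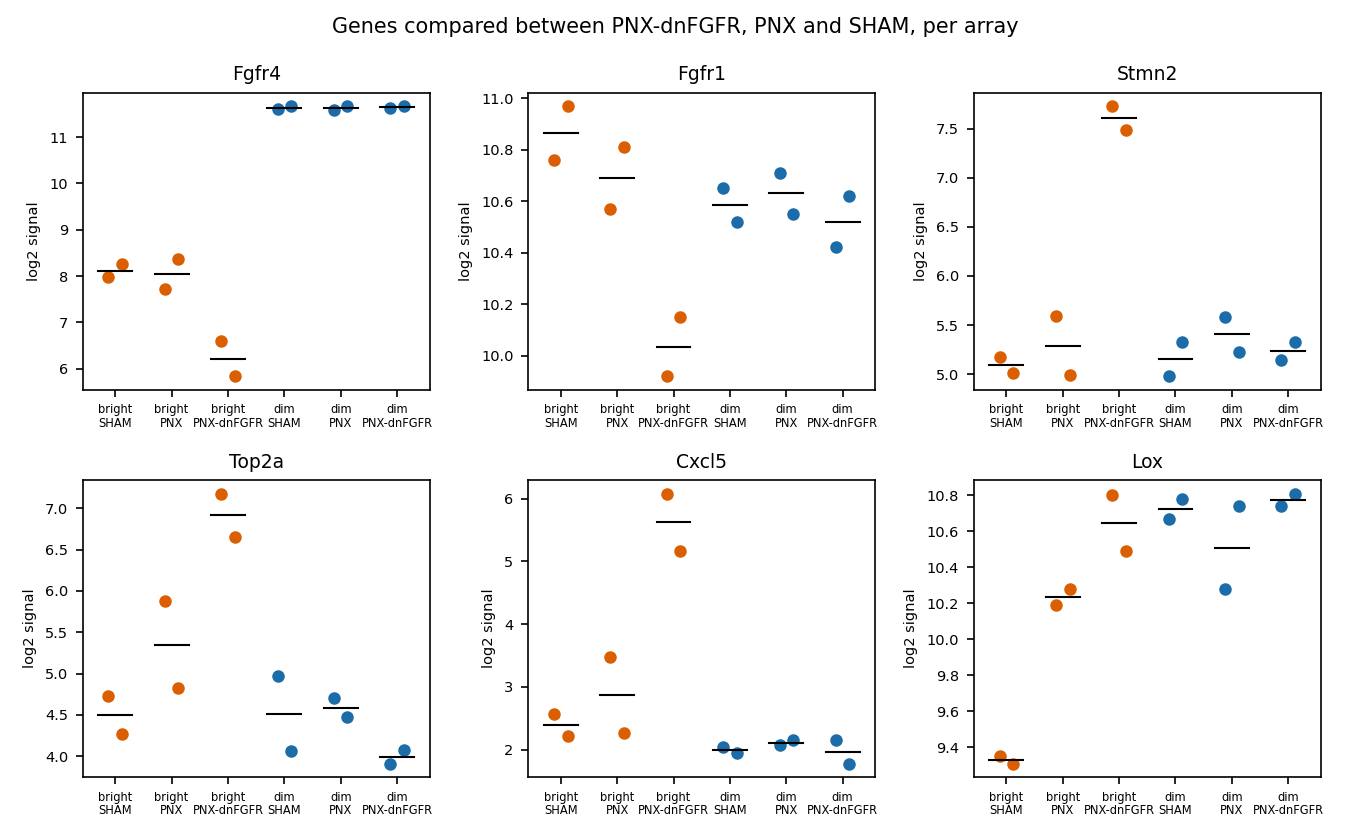
Log2 signal of 6 genes on each array (points, 2 per group) with the group mean (line), for bright (orange) and dim (blue) cells of the 3 conditions. In bright cells PNX-dnFGFR was lower than SHAM in Fgfr4 (-1.90) and Fgfr1 (-0.82) and higher in Top2a (2.41), Cxcl5 (3.22) and Lox (1.31), and Stmn2 was higher than in PNX (2.32).

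PNX-dnFGFR was also set against SHAM, which differs from it in the pneumonectomy and in the receptor. In bright cells Serpinb2, the gene of plasminogen activator inhibitor 2, rose by 5.16 (± 0.70 SE, n = 2 arrays per group, adjusted p = 0.011), Calcb by 4.66, Cdh2 by 4.28, Aqp3 by 4.18, Rarres1 by 3.58, Tnfrsf11b by 3.47, Trip13 by 3.40, Cxcl5 by 3.22, Trim9 by 2.98 and Chl1 by 2.94. Itga8, the integrin alpha 8 gene, fell by 2.08 (± 0.20, adjusted p = 0.0043), and Mlana had -2.34, Apod -2.33, Scube1 -2.08, Gpnmb -1.94, Hoxb7 -1.94, Fgfr4 -1.90, Cdo1 -1.89, Rgs2 -1.88 and Kcns3 -1.84. Acta2 did not pass (0.48 ± 0.45, adjusted p = 0.57), nor did Mki67 (1.62 ± 0.68, adjusted p = 0.2). Several of these genes lay below the filter in SHAM, Serpinb2 at 1.87 and 2.02. The held values were 2.0 for Serpinb2, 2.83 for Calcb, 3.53 for Cdh2, 2.04 for Trip13 and 0.52 for Cxcl5. The limma fit called 288 genes higher and 288 lower, 193 and 154 of them over 2-fold. These calls rest on few arrays. Without bright SHAM replicate 2 the count was 5, and the values of Itga8 (-1.98, adjusted p = 0.051), Slc7a10 (-1.36, adjusted p = 0.085), Birc5 (1.92, adjusted p = 0.06) and Dhcr7 (1.03, adjusted p = 0.072) kept their size without passing. The count was 106 without bright SHAM replicate 1, 129 and 65 without bright PNX-dnFGFR replicates 1 and 2, 346 without either dim PNX array, and 910 without either bright PNX array.

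Gene lists were compared between bright PNX-dnFGFR and SHAM cells in the same way. Of 17 alveolar fibroblast genes 8 fell in bright PNX-dnFGFR cells and 0 rose (11 and 0 adjusted over the list alone), led by Itga8, Slc7a10 (-1.32), Fgfr4 and Npnt (-1.34), with a median of -0.84. Camera gave an adjusted p of 3.3e-08, and adjusted p = 0.15 with an estimated correlation. Of 34 cell cycle genes 17 rose and 0 fell (29 and 0 adjusted over the list alone), led by Birc5 (1.93), Nusap1 (1.40), Rrm1 (1.23) and Top2a (2.41), with a median of 1.40, an adjusted p of 2.6e-17, and adjusted p = 0.26 with an estimated correlation. Of 17 cholesterol synthesis genes 6 rose and 0 fell (9 and 0 adjusted over the list alone), led by Dhcr7 (1.01), Cyp51 (1.70) and Idi1 (1.18), with an adjusted p of 4.6e-05, and adjusted p = 0.32 with an estimated correlation. Without bright SHAM replicate 2, 0 genes of these 3 lists passed, while the list medians over all arrays left out in turn ranged from -0.87 to -0.73, from 1.11 to 1.73 and from 0.50 to 0.67. PDGF and FGF pathway genes fell in 5 of 19 cases (7 adjusted over the list alone), with Fgfr4, Fgfr1 (-0.82), Fgf7 (-1.13) and Fgfr3 (-1.26), an adjusted p of 0.016, and adjusted p = 0.18 with an estimated correlation. Adventitial genes fell in 3 of 19 cases (4 adjusted over the list alone), Pcolce2 (-0.97), Gsn (-0.78) and Scara5 (-1.43), with an adjusted p of 9.5e-05, and adjusted p = 0.098 with an estimated correlation. IGF axis genes fell in 3 of 12 cases (7 adjusted over the list alone), Stc1 (-1.14), Igf2 (-1.25) and Irs1 (-0.70), with an adjusted p of 8.8e-04, and adjusted p = 0.17 with an estimated correlation. Mesothelial genes had a median of 0.81 with 0 of 11 past the threshold, over all genes or the list alone. Camera did not call them (adjusted p = 0.21). Their list mean was 1.18 and 1.62 on the bright PNX-dnFGFR arrays and 0.85 and 0.31 on the bright SHAM arrays. Cdh2 followed them on the bright PNX arrays, at 7.63 on replicate 1 and 3.80 on replicate 2. The other largest rises named for this comparison were higher on replicate 1 too. Calcb lay at 7.57 and 3.21, Rarres1 at 6.90 and 3.69 and Aqp3 at 6.67 and 4.35, in that order.

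Other lists in bright PNX-dnFGFR cells against SHAM were mostly not called by camera. Elastic fibre genes had 3 of 17 higher and 2 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.068), and cytokines and chemokines 4 of 21 higher and 0 lower (6 and 2, adjusted p = 0.15). Retinoid pathway genes had 3 of 15 higher and 1 lower (3 and 3, adjusted p = 0.26), and matricellular genes 2 of 21 higher and 0 lower (3 and 2, adjusted p = 0.56). Wnt pathway genes had 3 of 18 lower and 0 higher (4 and 2, adjusted p = 0.24), and TGF-beta and BMP pathway genes 2 of 21 lower and 0 higher (4 and 1, adjusted p = 0.052). Alveolar myofibroblast genes had 2 of 13 lower and 0 higher (5 and 1, adjusted p = 0.11). Glycolysis and hypoxia genes had 2 of 20 higher and 1 lower (7 and 3, adjusted p = 0.016, and adjusted p = 0.49 with an estimated correlation). Camera also called interferon response (median 0.51, adjusted p = 0.0045), oxidative phosphorylation (median 0.21, adjusted p = 0.0021) and endothelial genes (median -0.66, adjusted p = 0.0041). These had adjusted p = 0.48, 0.32 and 0.39 with an estimated correlation. Among elastic fibre genes Lox (1.31) and Fbn2 (2.33) rose and Ltbp4 (-0.80) and Efemp1 (-0.89) fell. The chemokine genes Cxcl5, Ccl7 (2.15), Ccl2 (2.73) and Cxcl1 (2.69) rose, as did Postn (1.58), Timp1 (1.53) and Plod2 (1.09). In the retinoid pathway Crabp2 (2.69), Rdh10 (2.54) and Cyp26b1 (0.93) rose and Adh1 (-0.84) fell. Hk2 (1.21) rose and Adm (-0.87) fell. The Wnt pathway genes Nkd2 (-1.06), Dkk3 (-0.61) and Wnt2b (-1.41) fell, and so did Bmp4 (-1.08), Bmp5 (-1.22), Aspn (-1.12), Hsd11b1 (-1.25), Mylk (-1.05) and G0s2 (-1.16). Of transcripts of other cell types, Il1r2 (1.79) and Cd14 (2.15) rose and Tmem100 (-0.79) and Cd8a (-0.81) fell. Held values in this comparison were 0.59 for Fbn2, 0.51 for Nusap1, 0.71 for Hk2, -0.39 for Slc7a10 and -0.10 for Cd8a. Of the 68 genes named here that passed in this comparison, 1 still passed without bright SHAM replicate 2, 24 without bright SHAM replicate 1, and 22 and 16 without bright PNX-dnFGFR replicates 1 and 2.

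**Figure D4:**
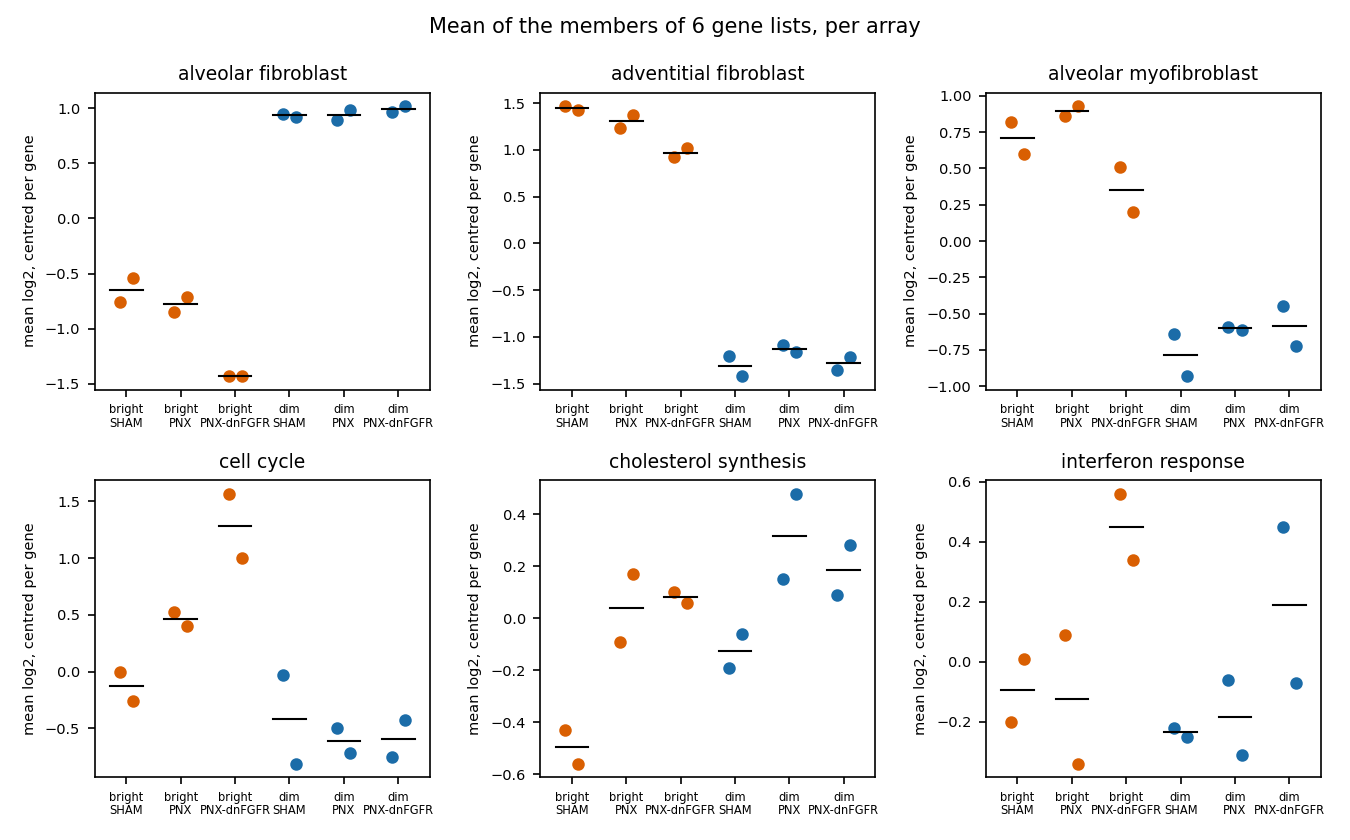
Mean log2 signal of the members of 6 gene lists on each array, each gene centred over the 12 arrays (points, 2 per group), with the group mean (line), for bright (orange) and dim (blue) cells of the 3 conditions. In bright cells alveolar fibroblast genes lay at -0.76 and -0.54 in SHAM and at -1.43 on both PNX-dnFGFR arrays, and cell cycle genes at 0.00 and -0.26 in SHAM and at 1.57 and 1.0 in PNX-dnFGFR.

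In dim cells PNX-dnFGFR differed from SHAM in 2 genes by limma, with 1054 at an unadjusted p below 0.05. Serpina3n rose by 3.43 (adjusted p = 3.6e-04) and Mpzl2 fell by 4.78 (adjusted p = 0.0024). Saa3 (6.02), Pianp (4.71), Hpca (2.42), Upk1b (-6.25), Galnt15 (-2.63) and Pglyrp1 (-1.87) did not pass. Held values were -2.25 for Mpzl2, which lay at 2.63 and 2.5 on the dim PNX-dnFGFR arrays, 2.3 for Pianp and 0.71 for Hpca. Other cells on the dim SHAM arrays were not tested as a source of the Mpzl2 fall here either. Without either dim PNX array Pianp passed (adjusted p = 0.0051), and without dim SHAM replicate 2 the count was 8. Cholesterol synthesis genes had a median of 0.28 (adjusted p = 5.2e-04, 0 of 17 past the threshold over all genes and 1 adjusted over the list alone), with adjusted p = 0.62 with an estimated correlation. PNX and PNX-dnFGFR share the SHAM arrays, so their changes against SHAM are correlated across genes by construction. The correlation was 0.68 in bright and 0.64 in dim cells, against 0.50 for simulated values with no effect.

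Whether an effect differed between bright and dim cells was tested as the difference of the effects. Limma called 0 genes for the PNX effect, with 495 at an unadjusted p below 0.05, and 0 for the effect of PNX-dnFGFR against PNX, with 909. The genes given next had an unadjusted p below 0.01 and were taken without a condition on overlap of their arrays. Among them the PNX effect, bright minus dim, was 4.16 for Mpzl2 (held value 2.25, adjusted p = 0.17), 2.30 for Cthrc1 (adjusted p = 0.17) and -5.55 for Saa3. The bright PNX and bright SHAM arrays overlap for Mpzl2 and Saa3. For PNX-dnFGFR the differences included 3.54 for Cldn10, 3.33 for Serpinb2 (held value 1.98), 3.10 for Trim9 and -1.85 for Fgfr4 (adjusted p = 0.45). Without bright PNX replicate 1 the second count was 50 and included Cldn10 (4.65), Serpinb2 (4.72) and Trim9 (3.77), and without dim SHAM replicate 1 Mpzl2 passed for the PNX effect (4.80, adjusted p = 0.027).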

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

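Of the tests in this part, the 3 on Pdgfra and those on the scaling and on cells of the dim gate and mesothelial cells in the bright gate were chosen only after the result was seen, as was leaving out arrays from the lists and clock genes. The other splits of the arrays were planned, but their fit was changed to the 6-group fit of the report after a first version had been seen, because that version called 0 genes for the real split. Counting apart the splits with 2 arrays in each group was added later still. The clock and glucocorticoid lists were written after some of their genes had been seen in these data, and before the tests on the others.

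Gene lists whose PNX effect differed between bright and dim cells by camera's test of the difference were the cell cycle (median difference 0.72, adjusted p = 3.5e-10), neutrophil and mast cell genes (1.66, adjusted p = 1.1e-04), pericyte genes (-0.39, adjusted p = 0.021), adventitial fibroblast genes (-0.37, adjusted p = 0.02), heat shock and unfolded protein genes (-0.12, adjusted p = 0.02) and endothelial genes (-0.43, adjusted p = 0.042). With an estimated correlation 0 of 31 lists passed. The pericyte, adventitial, heat shock and endothelial calls were lost without bright PNX replicate 1 (adjusted p = 0.13, 0.13, 0.19 and 0.24) or bright SHAM replicate 1 (0.072, 0.058, 0.17 and 0.058). The pericyte call was also lost without dim PNX replicate 1 (0.09) or dim SHAM replicate 2 (0.066), the adventitial call without dim SHAM replicate 2 (0.23), and the heat shock call without dim PNX replicate 2 (0.36) or dim SHAM replicate 1 (0.098). The endothelial call was lost without dim PNX replicate 1 (0.62), dim SHAM replicate 1 (0.39), bright SHAM replicate 2 (0.079) or either bright PNX-dnFGFR array (0.054).

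For the effect of PNX-dnFGFR against PNX, the lists that differed between the subsets were alveolar fibroblast (-0.71, adjusted p = 2.5e-09), cell cycle (0.76, adjusted p = 9.8e-09), elastic fibre (-0.49, adjusted p = 1.5e-05), glycolysis and hypoxia (0.37, adjusted p = 0.0037), alveolar myofibroblast (-0.55, adjusted p = 0.01), PDGF and FGF pathway (-0.52, adjusted p = 0.028) and oxidative phosphorylation (0.13, adjusted p = 0.028). With an estimated correlation 0 of 31 passed. Without dim PNX-dnFGFR replicate 1 the glycolysis, myofibroblast, PDGF and oxidative phosphorylation calls were lost (adjusted p = 0.06, 0.068, 0.068 and 0.068). So were the PDGF and oxidative phosphorylation calls without dim PNX replicate 2 (0.14 and 0.18), the glycolysis and oxidative phosphorylation calls without bright PNX-dnFGFR replicate 1 (0.058 and 0.063), and the last without bright PNX replicate 2 (0.082).

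Probe sets with no gene name, which no comparison above uses, held signals as well: of 7458 tested, 50 passed for PNX against SHAM over both subsets and 256 for PNX-dnFGFR against SHAM in bright cells.

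Other splits of the arrays were counted for 3 results. For bright against dim cells 5293 genes were called, and 1 of 100 splits, the real one, called as many, the highest other calling 1285. Most other splits put bright and dim arrays into 1 group, which widens the spread. Only 28 of the 108 splits with 2 arrays in each group were drawn, so this share does not exclude chance. For PNX against SHAM over both subsets 16 genes were called, and 1 of 34 splits, the real one, called as many, the highest other calling 2, which is the smallest share that 34 splits can give. Of these, 18 keep 2 arrays in each group as the real one does, too few for a share below 0.05. For PNX-dnFGFR against PNX over both subsets limma called 0 genes (1384 at an unadjusted p below 0.05, 3 with the mean of probe sets and 2 with a variance trend), so that 34 of 34 splits called as many holds by construction and decides nothing. The highest called 53: it sets bright PNX replicate 2 against the other 3 bright arrays and dim PNX replicate 1 against the other 3 dim arrays. Among the 18 splits with 2 arrays in each group the highest other called 1.

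Pdgfra was lower in all 6 libraries labelled bright, although the bright gate was set on the reporter of this gene. Dilution by RNA of epithelium, endothelium or macrophages would lower collagens as well and raise those cell types' genes, whereas the collagen list had a median of 0.23 and the 3 lists -0.03, -0.34 and -0.11, which argues against it. An exchange of the subset labels cannot be told apart from a true difference: alveolar myofibroblast genes other than Pdgfra were higher in libraries labelled bright, at a median of 2.28, but the labels do not say which gate holds myofibroblasts. Nor can a probe set that reads another transcript or background, since 1 probe set is named for the gene. Directions between the subsets are therefore those of the libraries as labelled.

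Alveolar fibroblast genes were lower in bright PNX-dnFGFR than in bright SHAM cells, and other genes higher. Members of the list changed by a median of -0.90 (median absolute deviation 0.48) relative to the 50 other genes nearest to each in level. A scaling of whole arrays would move genes of 1 level alike, so it alone does not give this difference. The medians of those other genes lay between -0.09 and 0.13, and quantile normalization holds them near 0. A shift of most genes that the normalization removed would look the same, so the test does not exclude it. Cells of the dim gate's mean profile make up at most 7.2% of bright SHAM by the fifth-lowest ratio of bright to dim signal among genes. That gene, Mpzl2, lay below the filter on the bright SHAM arrays, while Scube2 and Mapt, above it there, gave 6% and 6.2%. By the 7.2% bound the loss of such cells allows a rise of at most 0.11. Of the cell cycle list, fixed beforehand, 85.3% lay (with values below the filter set to it as well) over 2 standard errors beyond it, which argues against this loss as the whole cause of those rises. For the alveolar fibroblast genes it cannot be told apart from a change within the cells, since 41.2% of the list lay as far beyond the fall that the loss allows by this bound or any of the 3 next lower ratios, and 52.9% by the lowest, that of Slc7a10 alone. More mesothelial cells in the bright gate cannot be told apart from a change within the cells as a source of the higher genes either (median of their list 0.81), and the design does not separate the receptor from the pneumonectomy in this comparison.

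Clock genes differed between PNX and SHAM. The list of these genes and its directions were written after Per3, Ciart, Arntl and Nfil3 had been seen. Genes of the clock are not independent of these, so the others are no independent test. Of 10 genes with known clock phase not seen before the test, 10 differed in the direction that a shifted phase would give. None passed the threshold by itself. Per1 (1.24), Per2 (1.06), Dbp (0.96) and Npas2 (-1.08) were among them. Fry's p was 0.0032 over both subsets, 0.02 in bright and 0.013 in dim cells. The median difference in the listed direction was 0.90, and 0.72 to 1.02 with each array left out in turn. The p over both subsets counts bright and dim arrays as independent. If both gates of a replicate come from the same animals, which is not settled here, that p may be too small. Leaving out 1 array would then not remove an animal. Glucocorticoid exposure would raise its target genes, and 3 of 8 unseen targets were higher, Mt1 (1.22), Sgk1 (0.90) and Pdk4 (0.49), which meets a mark set beforehand against it, that no more than 1 in 2 are higher. After the result was seen this was read as open, since the other 5 lay between -0.20 and -0.02, within about 1 standard error of 0, and those seen before were Errfi1 (1.48), Tsc22d3 (0.84) and Zbtb16 (-1.98), so such exposure cannot be told apart from its absence. A shifted phase, as from another hour of harvest, is consistent with these values as a hypothesis, and as the sources used here give no hour, an hour and an effect of the operation on the clock stay open.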

How the results depend on the processing

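In this part, leaving out arrays from the list tests was chosen after the results were seen, and every other alternative was planned and run, except that only the groups compared is no change for the mean over the 3 conditions, which uses all of them. Of 105 counts of genes under alternatives other than leaving out arrays, 84 were within 1.5 times the reported count and 21 were not. For PNX against SHAM the count in dim cells, 5, was 2 with no filter, 13 with a variance trend and 0 with only the groups compared. In bright cells it was 1, and 0 with only the groups compared. Over both subsets it was 16, and 48 with the mean of a gene's probe sets, 35 with a trend and 1 with only the groups compared. For PNX-dnFGFR against PNX the count in bright cells, 1, was 37 with the stricter filter, 32 with a trend, and 0 with the mean of probe sets or only the groups compared. In dim cells it was 0, and 1 with the stricter filter, quantile normalization or a trend. Over both subsets it was 0, and 3 with the mean of probe sets and 2 with a trend. PNX-dnFGFR against SHAM in dim cells gave 2, and 1 with the stricter filter. The difference of the PNX effect gave 0, and 1 with the mean of probe sets. Bright against dim cells in PNX gave 2042, and 1270 with only the groups compared. Fitting only the groups compared leaves fewer arrays to estimate the spread, and for the other settings the cause was not tested.

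With each array left out in turn, the group that loses an array keeps 1, which is assumed to vary like the others. The counts then ranged from 4583 to 5298 for bright against dim cells as the mean, from 1229 (without bright SHAM replicate 2) to 2267 in SHAM, from 1110 (without dim PNX replicate 2) to 2042 in PNX and from 2429 (without bright PNX-dnFGFR replicate 1) to 3936 in PNX-dnFGFR. For PNX against SHAM they ranged from 0 (without bright PNX replicate 1) to 14 (without bright PNX replicate 2) in bright cells, from 1 (without dim PNX replicate 2) to 13 (without dim PNX-dnFGFR replicate 1) in dim cells and from 1 (without bright PNX replicate 1) to 27 (without dim PNX-dnFGFR replicate 1) over both. For PNX-dnFGFR against PNX they ranged from 0 (without bright PNX replicate 2) to 429 (without bright PNX replicate 1) in bright cells, from 0 to 1 in dim cells and from 0 to 129 (without bright PNX replicate 1) over both. PNX-dnFGFR against SHAM gave 5 (without bright SHAM replicate 2) to 910 (without bright PNX replicate 1) in bright cells and 2 to 8 (without dim SHAM replicate 2) in dim cells. The differences of effects gave 0 to 1 for PNX and 0 to 50 (without bright PNX replicate 1) for PNX-dnFGFR.

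For single named genes, 4912 values were computed under alternatives: 4307 kept direction and side of the threshold, 569 no longer passed, 34 newly passed and 2 had the other sign. These 2 were Acta2 between bright PNX-dnFGFR and SHAM, at -0.16 without bright PNX-dnFGFR replicate 1 and -0.12 without bright SHAM replicate 2, for a value of 0.48 that had not passed; over all arrays left out it ranged from -0.16 to 1.13. Of 434 list medians, 5 had another sign after quantile normalization, none of them of a list that camera called and each at most 0.03 in size.

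The lists called by camera numbered 12 for bright against dim cells as the mean, 12 in SHAM, 14 in PNX and 10 in PNX-dnFGFR. With an estimated correlation they were 1, 1, 1 and 0, and by fry 25, 17, 18 and 17. For PNX against SHAM they numbered 6 in bright cells, 4 in dim cells and 10 over both, with an estimated correlation 0, 0 and 0, and by fry 0, 0 and 3. For PNX-dnFGFR against PNX they numbered 12, 2 and 9, with an estimated correlation 0 each, and by fry 5, 0 and 3. For PNX-dnFGFR against SHAM they numbered 10 in bright and 6 in dim cells, with an estimated correlation 0 and 0, and by fry 7 and 0. For the differences they numbered 6 for PNX and 7 for PNX-dnFGFR, with an estimated correlation 0 and 0, and by fry 0 and 1. Camera with either correlation compares a list with other genes and fry does not.

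Deviations of bright and dim arrays of the same condition and number correlated at 0.003 to 0.128 over 3 pairs of groups, those of other conditions of a subset at -0.092 to 0.347, and the consensus correlation was 0.015. With 2 arrays per group these 3 pairs do not settle whether equal replicate numbers pair the samples. With a replicate block by number, the count for PNX-dnFGFR against PNX in bright cells was 0 in place of 1, and with a block by number within condition the difference of the PNX effect gave 1 in place of 0. Other counts with a replicate block stayed within 1.5 times. The signal over background limits genes near the lower end: 6024 genes were below the filter, and of a transcript with low signal on all arrays nothing is said here.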

Other observations

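The clock gene values here come from a list written after Per3, Ciart, Arntl and Nfil3 had been seen, and their comparisons with PNX-dnFGFR were added then.

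In PNX-dnFGFR against SHAM, 4 of the 10 clock genes not seen before the test differed in the direction that PNX had taken in bright cells, and 9 of 10 in dim cells. The fry p-values were 0.94 and 0.35. Both comparisons use the SHAM arrays that PNX was compared with. Against PNX over both subsets 0 of 10 differed in that direction, with a median signed difference of -0.75 and a fry p of 0.0079. That comparison shares the PNX arrays with PNX against SHAM, so the spread of these arrays alone would push the 2 in opposite directions. Nfil3, which is listed in the other direction, was higher in bright PNX-dnFGFR than in bright SHAM cells (1.32, adjusted p = 0.014). Between PNX and SHAM it had -0.04 in bright cells (adjusted p = 0.98) and -1.06 in dim cells (adjusted p = 0.12). Npas2, listed in the same direction as Nfil3, was lower in bright PNX-dnFGFR than in bright SHAM cells (-1.19, adjusted p = 0.041). That is the direction Npas2 had between PNX and SHAM in bright cells (-1.31, adjusted p = 0.3). Neither of these calls was tested with single arrays left out. Among the 10 genes, Tef had 0.69 between PNX and SHAM over both subsets, Hlf 0.83, Usp2 1.07, Nr1d2 0.70, Clock -0.24 and Bhlhe41 0.21, none past the threshold by itself (adjusted p = 0.088 to 0.65). Bhlhe41 had 0.01 in bright cells.

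Single transcripts of other cells varied between arrays. Hba-a1, a globin gene of red cells, ranged from 5.8 to 12.02, S100a9, a neutrophil gene, from 4.3 to 9.26, Nkain4, a mesothelial gene, from 7.13 to 11.13, Ager, an epithelial gene, from 9.04 to 10.95 and Ramp2, an endothelial gene, from 10.35 to 11.1.

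Changes against the shared SHAM arrays had a covariance across genes of 0.117 between PNX and PNX-dnFGFR in bright cells and 0.082 in dim cells, against 0.044 in each for simulated groups with no effect. The differences were 0.072 and 0.037. The simulated genes vary independently, so the differences include any deviation common to the SHAM arrays. What the effects themselves share was not separated from it. Genes are not independent replicates.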
